A study of Danio rerio with 3 samples.

How the data were processed

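The study measured small RNAs of whole zebrafish larvae (AB strain) at 7 days after fertilisation. The parents of these larvae had been kept, from 6 hours after fertilisation and for 90 days, in 0, 6.25 or 12.5 mg/L of a mixture of 6 β-diketone antibiotics. These were the fluoroquinolones ofloxacin, ciprofloxacin and enrofloxacin and the tetracyclines doxycycline, chlortetracycline and oxytetracycline. Each of the 3 groups had 1 library, so the series holds no replicate of any condition. Per the labels' protocols, total RNA was taken up in Trizol, libraries were made with the Illumina TruSeq small RNA kit, and single-end reads of 36 bp were sequenced on an Illumina HiSeq. The submitters' processing notes name the genome build Zv9. The aligner, the miRNA database release and the counting rules are not given in the sources used here.

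The deposited data were 4 tables, 1 with all 3 libraries and 3 with a pair of libraries each. Per the file headers, the authors deposited raw and normalised values for each sequence. The raw columns, as deposited by the authors, hold estimated counts (expected counts) of reads per sequence before any scaling, and 74.7% of them were whole numbers (tolerance 1e-09). How the fractional values arose is not given in the sources used here. In each library, the authors' normalised value (a signal on a common scale) was the count times 1 factor, which was 1.18 for the 0 mg/L library, 1.02 for the 6.25 mg/L library and 0.709 for the 12.5 mg/L library. The authors also deposited a ratio (fold), a log2 fold value and p-values (chi-square and Fisher tests, per the file headers) for pairs of single libraries. Those p-values compare libraries, not conditions. No value differed between the tables for the sequences they share. Each table has 1 emptied line.

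The three-library table had 1430 rows for 1202 distinct mature sequences. Rows with the same sequence were treated as 1 miRNA, under the name of the most abundant row. Of the 1202 sequences, 497 carried a zebrafish miRNA name, 488 a name from another species and 217 a candidate name given by the authors. In the names, R+1 or R-1 marks a sequence 1 nt longer or shorter at its 3′ end than the annotated form, and L the same at the 5′ end. A substitution is written as in G3T, with the annotated base, the position counted from 1 at the 5′ end of the read, and the base in the read. Positions in the deposited names were corrected for bases missing at the 5′ end, and were used unchanged where bases were added there. A position was accepted only where the read held the stated base. The marks were taken from the names and could not be re-derived. A sequence with a substitution may therefore be another member of its family, and leaving out substituted sequences may remove such members. A substitution was called early at read position 1 to 8, a limit chosen after the data were seen. For 3 sequences the position could not be placed.

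The log2 ratio of a pair of libraries was taken from the deposited normalised values with a pseudocount of 1, so it understates differences of scarce sequences. The 471 sequences with a mean of 10 or more normalised reads over the 3 libraries were compared, and they held 99.98% of all counts. With 1 library per group there was no test, and a fixed size rule of at least 2-fold was used. The 95% intervals of a ratio are exact (Clopper-Pearson) intervals of the rounded counts. Intervals cover counting error only, because reads amplified by PCR are not independent molecules and because larvae differ.

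The miRNAs named were set before the data were examined. They were the 8 highest and the 8 lowest log2 ratios of each comparison among zebrafish-named sequences with a mean of 100 or more, the 5 most abundant miRNAs, and the 3 most abundant members of each list. The same ranking among sequences without a substitution was added after the data were seen, and other names were chosen after their values were seen. The 18 lists, also set beforehand, group families by tissue or function: muscle, nervous system, photoreceptor and hair cell, liver, intestine and kidney epithelium, skin and other epithelium, pancreas, red blood cell, immune cell, endothelium, smooth muscle and mesenchyme, let-7 family, maternal-to-zygotic (miR-430), miR-17-92 and paralogs, Hox cluster, stress response, lipid and metabolism, and gonad. For lists with at least 3 sequences, the median log2 ratio was placed among 10000 random lists of the same size matched on abundance in 10 classes. That percentile describes these libraries and is not a p-value. Of the 16 lists with a percentile, 0.8 per comparison would lie outside the central 95% by chance if sequences were independent. Lists hold several forms of the same family, which are not independent, so chance could place more lists outside.

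For the direction shared by both doses, 1000 sets of unchanged libraries with a common control were simulated at counting error. The alternatives were a pseudocount of 0.5 or 10, no filter or a mean of 100, scaling to equal totals, by the median of ratios or by a mean trimmed by 30% on each side, each deposited row counted, zebrafish names only, and size rules of 1.5-fold and 3-fold. Added after the data were seen were the exclusion of substituted sequences, the sum of all sequences of a miRNA arm, and a correction for sequence length. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

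The size rule was tested on simulated data made from the real means and depths, for 12.5 against 0 mg/L with 471 sequences. It found 99.0% of 100 sequences planted with a 4-fold difference and 5.00% of 100 planted with a 1.5-fold difference. It named 0.738% of 271 unchanged sequences. The simulated counts held counting error only, without spread between libraries or larvae. The 0.738% is therefore no measure of how often unchanged sequences pass 2-fold in real single libraries. A list planted at 2-fold in the same comparison had a median log2 ratio of 1.00, above all random lists, and 4 of 45 other list results lay outside the random range. Among the tested sequences, 6 had exactly the same counts in all libraries as another sequence, 4 of them in the miR-430 list. Whether reads were shared between such forms was not tested, and values of close paralogs are uncertain to that extent. The assembly GRCz12tu was used only for which miRNA genes neighbour each other, not for positions.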

Results

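The data asked which miRNAs differ in 7-day-old zebrafish larvae whose parents were exposed to β-diketone antibiotics. The larvae belonged to the next generation (F1) in all 3 groups. Counts summed to 4534557 in the library of parents at 0 mg/L, 5099264 at 6.25 mg/L and 6041242 at 12.5 mg/L. Sequences above 0 numbered 824, 838 and 900 in that order. There was 1 library per group, so no difference below has a replicate check, and "higher" and "lower" describe these libraries.

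The most abundant miRNAs were miR-30e-5p (397282 normalised reads at 0 mg/L, 313893 at 6.25 and 330345 at 12.5), the C21T form of miR-26a-5p, miR-181a-5p, miR-10b-5p and miR-10c-5p. The 10 most abundant sequences took 49.3% of counts at 0 mg/L (95% exact binomial interval 49.3 to 49.4), 48.3% at 6.25 mg/L (48.3 to 48.4) and 44.2% at 12.5 mg/L (44.2 to 44.3). Sequences with names from other species took 2.76% (2.74 to 2.77), 3.41% (3.40 to 3.43) and 4.12% (4.10 to 4.13). Sequences with a substitution at read position 1 to 8 took 0.148% (0.145 to 0.152) at 0 mg/L, 0.151% (0.148 to 0.155) at 6.25 mg/L and 0.412% (0.407 to 0.417) at 12.5 mg/L. These shares count reads and carry the same counting limits as the ratios below.

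The first comparison set larvae of parents at 6.25 mg/L against those of control parents. Among the 8 lowest ratios were those of the 3p arms of miR-19, members of the miR-17-92 cluster linked to cell proliferation. miR-19a-3p (TGTGCAAATCTATGCAAAACTGA) stood at 36019 normalised reads in the control library and 14910 at 6.25 mg/L, 2.42-fold lower (ratio interval 0.406 to 0.422). miR-19b-3p, read as TGTGCAAATCCATGCAAAACTG, had 102518 and 50295, 2.04-fold lower (0.485 to 0.496). miR-731, which with its neighbour miR-462 belongs to the stress list as a hypoxia- and interferon-linked pair in fish, was 2.10-fold lower (1256 and 599; 0.430 to 0.528), and miR-462 was 1.60-fold lower (4292 and 2682; 0.594 to 0.657).

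Higher at 6.25 mg/L was miR-144-3p of red blood cells, read with 1 nt more at its 5′ end (304 and 620, 2.04-fold, interval 1.76 to 2.37). Also higher were the 3p arms of miR-430, the family that clears maternal mRNA in the early embryo. miR-430b-3p 2 nt shorter at its 3′ end had 155 and 298 (1.92-fold, 1.57 to 2.39), and miR-430a-3p 1 nt shorter had 142 and 226 (1.58-fold, 1.27 to 2.01). The 5p arm of the endothelial miR-126a was 1.58-fold higher (4641 and 7337). Other low values were those of miR-145-5p of smooth muscle (1571 and 925), miR-301a (29160 and 18880) and the immune-cell miR-155 (324 and 215). A miR-21b-3p sequence of the stress list, named for salmon, had 2480 and 6610 (2.66-fold, 2.54 to 2.80). The largest ratio of the named set was that of the T16A form of miR-430b-5p, at 43.1 and 173 (3.94-fold, 2.82 to 6.00).

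In all, 12 of 471 sequences were at least 2-fold higher and 12 at least 2-fold lower, and 83.4% lay within 1.5-fold. Of those past 2-fold, 7 higher and 11 lower sequences had counting intervals that exclude 1. Scaling by the median of ratios gave 9 higher and 16 lower. Among 347 sequences without a substitution, 7 were higher and 10 lower. In the authors' deposited table, 272 of 1203 sequences had a Fisher p-value below 0.05 for this pair of libraries.

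Of the lists, the miR-430 list stood apart at 6.25 mg/L, with 31 sequences and a median log2 ratio of 0.34, at the 99.9th percentile of random lists. Of its members 26 were above 0 and 5 below, and 2 were at least 2-fold higher. Without substituted sequences 18 remained, with a median of 0.32 at the 98.7th percentile. miR-430a-3p had 757 and 931 and its G22T form a log2 ratio of 0.53, while the most abundant member, miR-430b-5p, had 1279 and 1144. The stress list had a median of 0.32 with 2 members at least 2-fold higher and 2 at least 2-fold lower (96.8th percentile). The miR-17-92 list had a median of 0.14 (68.3rd percentile) with 4 of 32 sequences at least 2-fold lower. Besides miR-19a-3p and miR-19b-3p these were a salmon-named miR-19a-3p with T11C, chosen after its value was seen, and the T3A form of miR-19d-3p. The T11C sequence has C at read position 11, as miR-19b-3p does, so it may be a form of miR-19b-3p and not a further member. The cluster partners miR-20a-5p (28261 and 25800) and miR-92a-3p (56067 and 46804) were 0.13 and 0.26 lower on the log2 scale.

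The other lists lay within the range of random lists at 6.25 mg/L. Their medians were 0.04 for muscle, 0.15 for the nervous system, -0.16 for photoreceptor and hair cell, 0.38 for liver, 0.04 for intestine and kidney epithelium, -0.10 for skin, 0.33 for pancreas, -0.05 for immune cell, 0.11 for endothelium, -0.06 for smooth muscle, -0.01 for let-7 (10 forms under names from other species, as the main zebrafish let-7 forms were not analysed here), 0.07 for Hox cluster and 0.05 for lipid and metabolism. The red blood cell list held miR-144-5p (2982 and 3104) beside miR-144-3p. miR-202-5p, the gonad miRNA, had 75.5 and 91.9. Abundant tissue miRNAs ranged more widely. A salmon-named miR-128-3p of the nervous system had 43037 and 66764 (log2 ratio 0.63), and miR-199-3p 1 nt shorter at its 5′ end (0.48), miR-122 of liver (0.39) and miR-216b of pancreas (0.34) were also higher. miR-205-5p of skin was lower (-0.37), while miR-133a-3p of muscle (111353 and 114309), miR-9-5p of the nervous system (0.02), miR-200a-3p of epithelia (0.07) and miR-140-3p of cartilage (-0.09) were close to control.

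**Figure D1:**
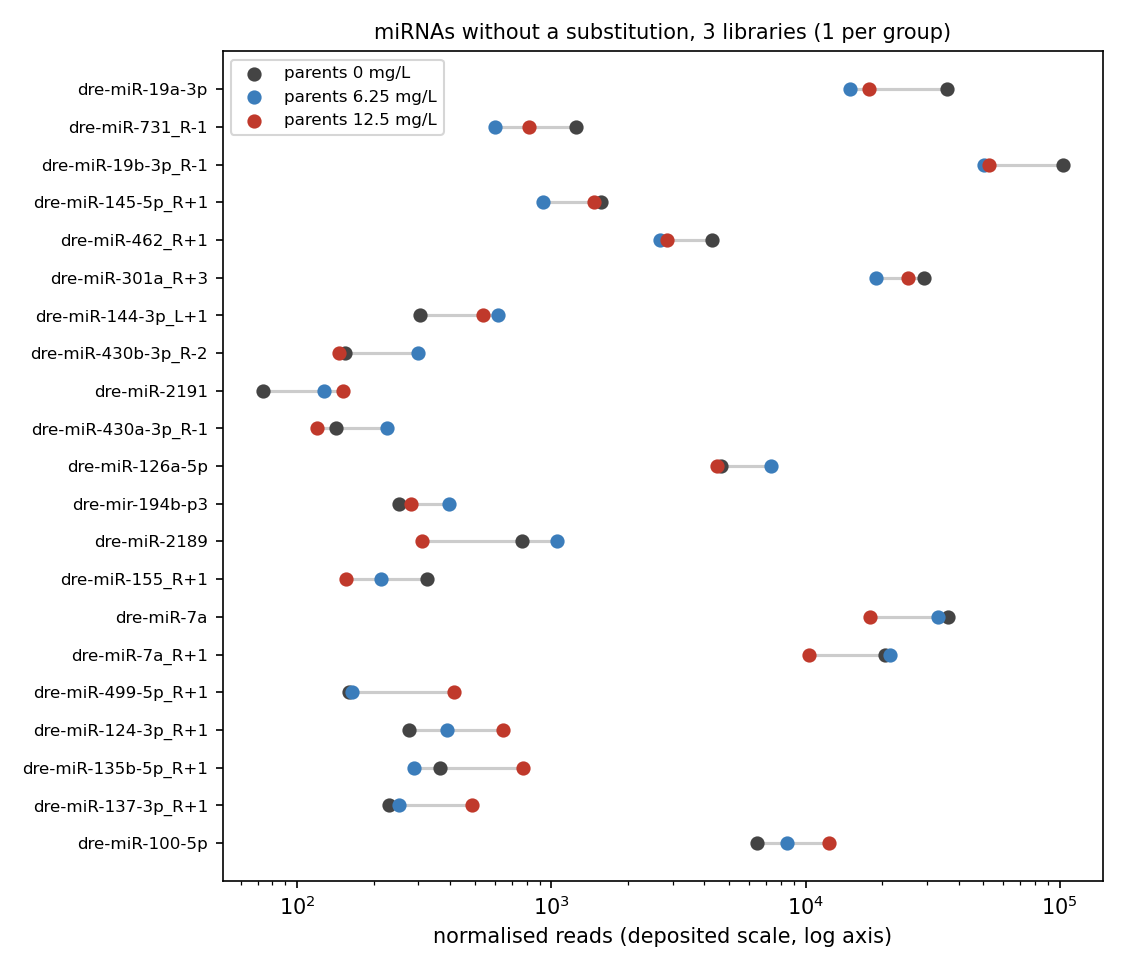
Normalised reads (log axis) of zebrafish miRNAs without a substitution that had the most extreme ratios to the control library, 1 point per library. Both treated libraries lie below the control for miR-19a-3p and miR-19b-3p, and the 12.5 mg/L library stands apart for miR-7a, miR-2189 and the longer form of miR-499-5p.

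The second comparison set 12.5 mg/L against 0 mg/L. miR-19a-3p (17845 at 12.5 mg/L; 2.02-fold lower, ratio interval 0.487 to 0.504) and miR-19b-3p (52749; 1.94-fold lower, 0.510 to 0.520) were again among the 8 lowest. miR-7a, known from neurons and endocrine cells, had 36196 and 17925 (2.02-fold lower, 0.487 to 0.504), and its form 1 nt longer 20448 and 10286 (1.99-fold lower, 0.492 to 0.514). miR-2189 had 770 and 310 (2.48-fold lower, 0.356 to 0.455), and miR-155 had 324 and 156 (2.07-fold lower, 0.401 to 0.576). miR-190b and miR-181b-5p were 1.72-fold and 1.75-fold lower. Among sequences without a substitution, the highest were the 3′-extended forms of miR-499-5p of slow and heart muscle (160 and 416, 2.59-fold, 2.15 to 3.15), miR-124-3p of neurons (276 and 647, 2.34-fold, 2.03 to 2.72), miR-135b-5p (363 and 771, 2.12-fold) and miR-137-3p of neurons (231 and 488, 2.11-fold). With the unsubstituted zebrafish-named forms of an arm summed, miR-124-3p had 9832 and 15151 and miR-137-3p 4182 and 5349. For miR-499-5p the sums were 3440 and 5242. These ratios were smaller than those of the extended forms. miR-100-5p had 6466 and 12341.

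The highest ratios of the fixed rule belonged to substituted sequences. The G3T form of miR-1, the main miRNA of muscle, had 479 and 5116 (10.7-fold, 9.66 to 11.8), and the G3T form of miR-206-3p, also of muscle, had 151 and 1584 (10.4-fold, 8.78 to 12.6). The 6.25 mg/L library had 531 and 139 for these. The T3A form of miR-19d-3p had 72.5 and 274, and the T1G form of the brain miRNA miR-9-5p 1300 and 4119. The unsubstituted full-length forms of miR-1 and miR-206-3p were not analysed here, so a share of substituted reads cannot be given for them. miR-9-5p without a substitution was lower at 12.5 mg/L (log2 ratio -0.56).

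At 12.5 mg/L, 51 of 471 sequences were at least 2-fold higher than control and 20 at least 2-fold lower, and 65.4% lay within 1.5-fold. Among the 347 sequences without a substitution, the numbers were 16 higher and 18 lower. Of 38 sequences with an early substitution, 21 were higher and 1 lower. Scaling to equal totals shifted each log2 ratio of this comparison by 0.32 and gave 89 higher and 10 lower, or 42 and 10 without substituted sequences. Scaling by the median of ratios shifted them by -0.12 and gave 44 higher and 26 lower, or 12 and 23 without substituted sequences. The balance of higher and lower sequences thus depended on the scaling. miR-19a-3p, miR-7a and miR-2189 stayed below 0 under every scaling tried (highest log2 ratios -0.69, -0.69 and -0.99). In the authors' deposited table, 383 of 1203 sequences had a Fisher p-value below 0.05.

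**Figure D2:**
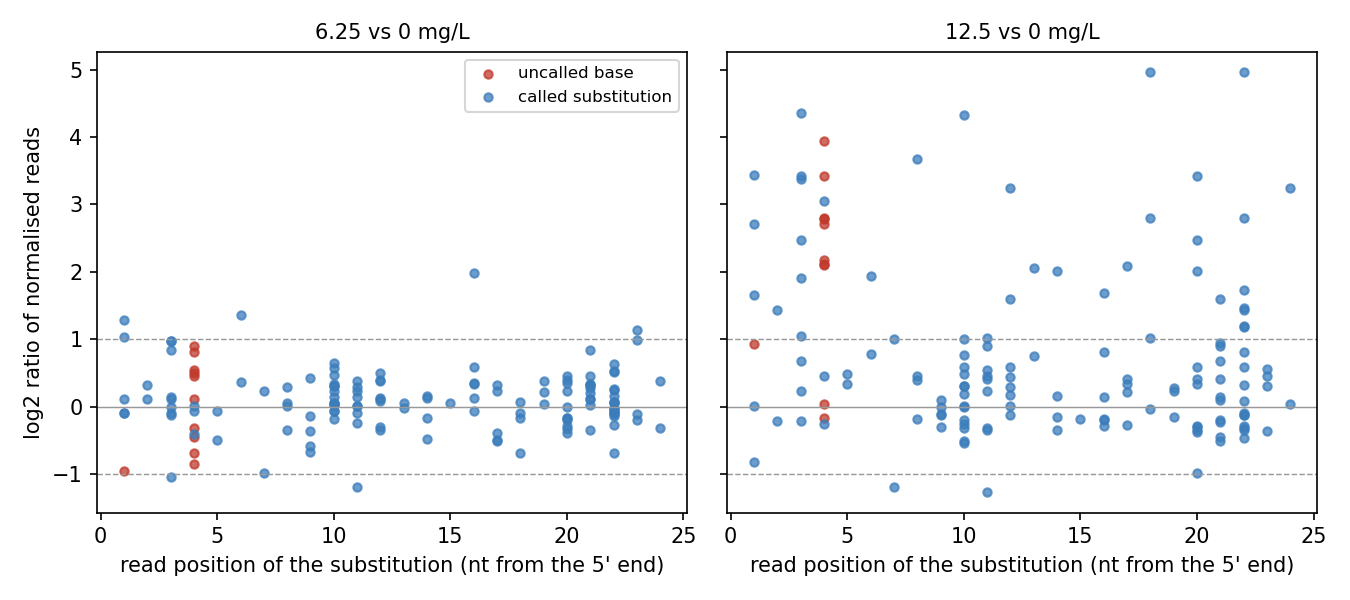
Log2 ratio of normalised reads against the read position of each substitution, for tested sequences with a placed substitution, in both comparisons with the control library; dashed lines mark 2-fold. At 12.5 mg/L, 8 of 11 sequences with an uncalled base are at least 2-fold higher, against 0 of 11 at 6.25 mg/L.

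The muscle list was higher at 12.5 mg/L, with 18 sequences, a median log2 ratio of 0.52 at the 99.1st percentile, and 5 members at least 2-fold higher. Its sequences without a substitution had a median of 0.48 (10 sequences, 97.4th percentile), just inside the random range, and only 1 of them, miR-499-5p, was at least 2-fold higher. miR-499-5p 1 nt shorter had 3281 and 4825, and miR-133b-3p with C10T had 3719 and 5619, whereas miR-133a-3p, the most abundant, had 111353 and 115249. The list median stayed above 0 under every scaling (lowest 0.38). The lipid and metabolism list was lower, with 15 sequences, a median of -0.43 at the 0.275th percentile, and 11 members below 0. With no filter on low values its median was -0.15 (25 sequences, 4.82nd percentile), inside the random range. miR-103 had 25692 and 15444 (1.66-fold lower), miR-148 had 4981 and 3559, and miR-27b-3p went the other way with 18275 and 21158. No member reached 2-fold, and the median stayed below 0 under every scaling (highest -0.11).

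The Hox cluster list had a median of -0.33 (14 sequences, 2.78th percentile) and, without substituted sequences, -0.42 (11 sequences, 1.42th percentile), but -0.01 with equal totals. miR-10b-5p was 1.63-fold lower (336155 and 206797) and miR-10c-5p had 278020 and 188598. For the miR-430 list the median was 0.01 (11.2nd percentile), with 4 of 31 sequences at least 2-fold higher, and 0 of 18 without substituted sequences. Medians of the others within the random range were 0.21 for the nervous system, 0.28 for photoreceptor and hair cell, 0.29 for liver, -0.10 for intestine and kidney epithelium, 0.07 for skin, 0.01 for pancreas, 0.06 for immune cell, 0.08 for endothelium, 0.26 for smooth muscle, 0.04 for the same let-7 forms, 0.19 for miR-17-92 and 0.32 for stress. The liver miRNA miR-122 had 18653 and 12901, miR-21 of the stress list had a log2 ratio of -0.45, and miR-146a of immune cells had 33181 and 44610. miR-144-5p was lower (2982 and 1809) and miR-144-3p higher (304 and 540). miR-202-5p had 75.5 and 113.

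**Figure D3:**
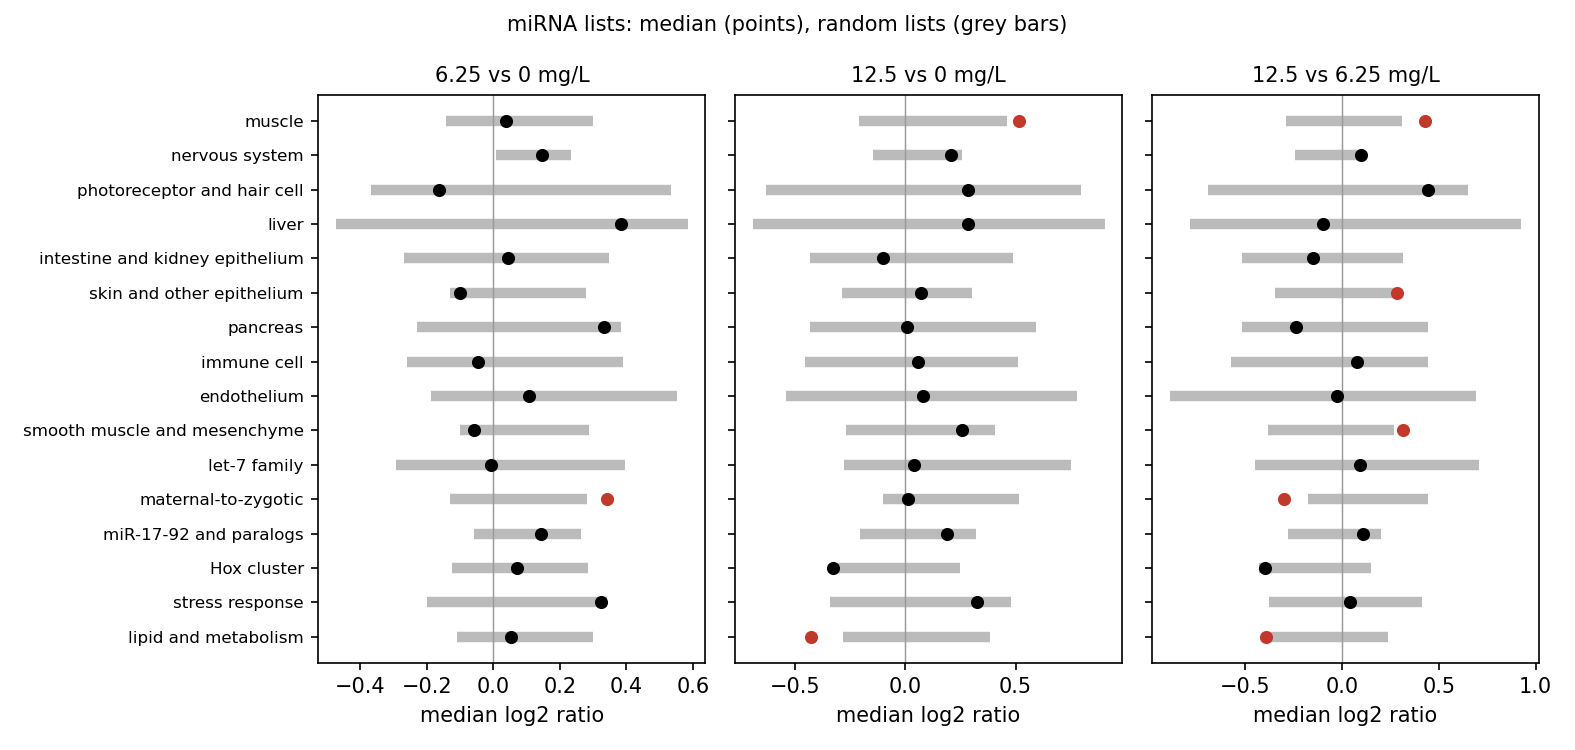
Median log2 ratio of each miRNA list (points) with the central 95% of random lists matched on size and abundance (grey bars), in the 3 comparisons; red points lie outside it. The miR-430 list is at 0.34 at 6.25 mg/L and the muscle list at 0.52 at 12.5 mg/L, each against control.

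The third comparison, 12.5 against 6.25 mg/L, does not use the control library. miR-2189 was 3.40-fold lower at 12.5 mg/L (1054 and 310; ratio interval 0.262 to 0.329), miR-7a with 1 nt more 2.10-fold lower (21551 and 10286) and the short miR-430b-3p 2.03-fold lower (298 and 146; 0.408 to 0.587). miR-190b had 45233 and 23747, miR-122 had 24393 and 12901, and miR-219-5p, a miRNA of myelin-forming glia, had 15792 and 8533. Higher at 12.5 mg/L were the G3T forms of miR-206-3p (11.3-fold) and miR-1 (9.61-fold), miR-135b-5p (2.67-fold, 2.35 to 3.06) and the longer miR-499-5p (2.52-fold, 2.12 to 3.03). miR-125b-5p had 12045 and 20452. miR-19a-3p and miR-19b-3p had log2 ratios of 0.26 and 0.07.

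In this comparison 52 sequences were at least 2-fold higher and 16 lower. Scaling to equal totals shifted the log2 ratios by 0.28 and gave 75 and 8, or 33 and 8 without substituted sequences, where the main setting gave 19 and 16. The miR-430 list was lower, with a median of -0.30 (0.295th percentile) and -0.46 without substituted sequences (0.030th percentile), the former close to 0 (-0.01) with equal totals. The lipid and metabolism list had a median of -0.39 (2.28th percentile; -0.11 with equal totals), with 14 of 15 members below 0. It was inside the random range without substituted sequences (4.84th), with zebrafish names only (4.50th) and with no filter (4.78th). The muscle (0.43, 99.3rd percentile), smooth muscle (0.31, 98.9th) and skin (0.28, 97.8th) lists were higher. Without substituted sequences these 3 medians were 0.19, 0.09 and -0.13, inside the random range. The remaining lists with a percentile lay inside it, from -0.39 for the Hox cluster to 0.45 for photoreceptor and hair cell. The red blood cell list, with 2 sequences and no percentile, had a median of -0.49. In the authors' deposited table, 359 of 1203 sequences had a Fisher p-value below 0.05.

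Across both doses, 7 sequences were at least 2-fold lower than control at each dose and 6 higher. Independent lists of these sizes would share 0.510 and 1.30, and simulated unchanged libraries with a common control gave a median of 0 (0 to 1) and 1 (0 to 4). The simulation held counting error only and few of its sequences passed 2-fold at all, so small shared numbers were nearly certain there. The 7 lower sequences, named because they are few, included miR-19a-3p and a salmon-named miR-19a-3p with T11C. The others were miR-486-5p, miR-146a, miR-21-5p and miR-186 under mammalian names, and a candidate sequence. Only miR-19a-3p among them carried a zebrafish name. The T11C sequence has C at read position 11, as miR-19b-3p does, so it may be a form of miR-19b-3p. Without substituted sequences 6 were lower and 2 higher. Higher at both doses were substituted forms of miR-430b-5p, miR-132-5p, miR-18b-5p and miR-7977, with miR-34b and miR-738. At 6.25 mg/L the counting intervals of miR-132-5p (0.577 to 29.9), miR-18b-5p (0.682 to 7.53), miR-34b (0.937 to 5.22) and miR-738 (0.706 to 10.3) include 1, and with a pseudocount of 10 only 1 sequence was higher at both doses. Over the 471 sequences the log2 ratios at both doses had r = 0.27, against 0.58 in the simulation, and a covariance of 0.115 against 0.040. Genes are not independent replicates, and part of the overlap may come from the single shared control library.

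Of the 71 sequences at least 2-fold different between 12.5 and 0 mg/L, 41 (57.7%) had their 6.25 mg/L value between the other values. In simulated unchanged libraries too few sequences passed 2-fold (median 4) to compare that share. Over all 471 sequences, 39.5% had the 6.25 mg/L value in between, against 32.5% in the simulation (28.2 to 36.5). The simulation held counting error only, without spread between libraries or larvae, so this difference does not show a dose order. In the order of doses, miR-155 had 324, 215 and 156, and miR-124-3p in its longer form 276, 388 and 647, while miR-2189, at 770, 1054 and 310, was not in dose order. The summed unsubstituted forms of miR-124-3p had 9832, 13512 and 15151. The authors' deposited table of all 3 libraries had 439 of 1202 sequences with a chi-square p-value below 0.05.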

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

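The alternatives without substituted sequences, with arms summed and with the length correction were chosen after the data were seen. Main counts of sequences at least 2-fold higher and lower were 12 and 12 at 6.25 mg/L, 51 and 20 at 12.5 mg/L, and 52 and 16 between the doses. Counts that moved by more than 1.5 times were the following. A pseudocount of 10 left 3 higher at 6.25 mg/L, 12 lower at 12.5 mg/L, 5 lower between doses and 1 higher at both doses. With no filter, which adds scarce sequences, there were 116 and 103, 175 and 122, and 156 and 116. A mean of 100 or more, which tests fewer, gave 3 and 6, 18 and 6, and 15 and 4, with 1 higher and 3 lower at both doses and 12 in dose order (41 in the main setting). Zebrafish names alone gave 7 and 4, 33 and 6, and 31 and 8. The 1.5-fold rule gave 43 and 35, 107 and 56, and 91 and 69. The 3-fold rule gave 1 and 0 at 6.25 mg/L, 4 lower at 12.5 mg/L, and 34 and 5 between doses. Equal totals gave 89 and 10 at 12.5 mg/L and 8 lower between doses. Without substituted sequences, 7, 16 and 19 were higher in the 3 comparisons, 2 were higher at both doses and 21 lay in dose order. Summed arms gave 22 higher in each comparison with 12.5 mg/L, and the length correction 7 higher at 6.25 mg/L. The cause of the moves under scaling and summing was not tested.

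No named miRNA past 2-fold changed sign under any alternative run. That outcome was nearly fixed in advance. The scalings shifted log2 ratios by at most 0.32, and the filters and choices of rows or names left each ratio as it was. Summed arms, which could change a ratio more, were not run for single named miRNAs. Of 218 named ratios, 165 left their counting interval with equal totals and 138 with the length correction. Of the list medians outside the random range, the skin list between the doses (0.28) changed sign with a mean of 100 or more (-0.13), with zebrafish names (-0.10) and without substituted sequences (-0.13). With random lists matched also on length, the stress list at 6.25 mg/L reached the 99.2nd percentile and the Hox cluster list at 12.5 mg/L the 0.590th, outside the central 95%, while between the doses the skin list (96.8th) and the lipid and metabolism list (2.54th) came inside it. No paired analysis was possible because each group has 1 library.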

Other observations

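Some hairpins differed between libraries in the balance of their arms. For miR-19a, the 5p arm had 603 normalised reads at 0 mg/L and 551 at 6.25 mg/L, against 36019 and 14910 for the 3p arm. For miR-144 at 0, 6.25 and 12.5 mg/L, the 5p arm had 2982, 3104 and 1809 and the 3p arm 304, 620 and 540, and for miR-145 the 5p arm had 1571, 925 and 1468 and the 3p arm 44.2, 72.5 and 83.0. The 3p arm of miR-144 is here only 1 form, with 1 nt more at its 5′ end, so its arm balance is uncertain. Of 50 zebrafish hairpins with both arms at a mean of 10 or more, the log2 ratio of 5p to 3p reads differed from control by at least 1 in 4 at 6.25 mg/L and in 3 at 12.5 mg/L. miR-10b was 1 of the 4, with 336155, 246543 and 206797 for the 5p arm and 888, 1348 and 892 for the 3p arm. These miRNAs were chosen after their values were seen.

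Sequence length also separated the libraries. Among sequences without a substitution, the median log2 ratio at 6.25 mg/L was 0.30 for 59 sequences of 21 nt or less, 0.18 at 22 nt, 0.02 at 23 nt and -0.37 for 44 sequences of 24 nt or more. At 12.5 mg/L the medians were 0.09, -0.08, 0.16 and 0.08. Between the doses, 12.5 against 6.25 mg/L, they were -0.24, -0.17, 0.10 and 0.49. The ratios given for short and long sequences, such as the 21 nt miR-144-3p and the 25 nt miR-301a, were not corrected for this trend. Sequences of miRNA families from the placental imprinted cluster (a list written after part of the data were seen) had 58.5, 48 and 35 counts at 0, 6.25 and 12.5 mg/L, a share ratio of 0.449 between 12.5 and 0 mg/L (interval 0.289 to 0.701) and of 0.730 between 6.25 and 0 mg/L (0.491 to 1.10, which includes 1). For other families known from mammals the share ratios were 0.381 (0.317 to 0.456) and 0.463 (0.386 to 0.554). The miR-486-5p sequence named for macaque had 322, 139 and 84.0 normalised reads, and the zebrafish-named miR-146a 33181, 41691 and 44610 against 46.0, 17.9 and 8.04 for the horse-named form, the macaque-named and horse-named forms chosen after their values were seen. Of the 1202 sequences, 174 were at 0 in all 3 libraries, 121 of them under names from other species.

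Of the tests below, those on length for miR-430 and on the percentile of miR-19 among like sequences were written before their results were seen, and the others after. For miR-19, the bound for the neighbouring arms was rewritten after a first bound had decided nothing, and the test on medians of like sequences was added after the first test had come out on the side of base composition and length.

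At 12.5 mg/L, 35 of 124 substituted sequences were at least 2-fold higher than control, against 16 of 347 others, while 42 of the 124 were below 0. The 70 sequences with an uncalled base all (100%) had it within read positions 1 to 5, and the 11 that were tested had a median log2 ratio of 2.18 at 12.5 mg/L, a value that RNA editing does not explain since no RNA base is read as uncalled; missing calls in the first read cycles are a candidate explanation for them. Of called substitutions, 48.1% of 27 at positions 1 to 8 were at least 2-fold higher (exact interval 28.7 to 68.1) against 16.5% of 85 from position 9 on (9.31 to 26.1), so early miscalls may account for part of the G3T signal of miR-1 and miR-206-3p. That leaves out the later substitutions, whose 16.5% lies above the 4.61% of unsubstituted sequences (2.66 to 7.38). All these intervals treat sequences as independent, though several are forms of the same miRNA. The largest log2 ratio of a placed substitution at 12.5 mg/L was of a late form, miR-152 with T18G and G22T (4.96). miR-203b-3p with T10C had 4.32. At 6.25 mg/L they had 0.07 and -0.19. miR-152 with G22T alone had -0.46 at 12.5 mg/L. The strongest rises were thus not confined to early positions. Some of these later forms may be other family members under a near name, as with T11C of miR-19a-3p. Their share is thus no measure of miscalls or editing alone. Depth is argued against, because the share of reads with an early substitution was 2.78 times that of control (2.71 to 2.86), and whether parental exposure altered any called substitution was not tested.

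Against random lists, the miR-430 list was higher at 6.25 mg/L only. With equal totals its median between the doses was close to 0 (-0.01), so the contrast of the doses depends on the scaling. The trend with length does not account for the 6.25 mg/L value as a whole, since the list stayed at the 99.6th percentile of length-matched random lists. Those lists were matched on abundance more coarsely than the main ones. Nor do substituted members, since without them it stood at the 98.7th. All these random lists drew single sequences, whereas the miR-430 members are forms of 1 family, 4 of them with counts equal to another sequence. The percentiles may therefore overstate how far the list stands apart. A younger stage of these larvae could raise miR-430, and it stays untested: the let-7 list (27.7th percentile) held only scarce forms under names from other species, without the main zebrafish let-7. With 1 library, stage and parental exposure cannot be told apart here.

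The 3p arms of miR-19a and miR-19b were lower at both doses, by a mean log2 ratio of -1.07. Less of the shared transcript is argued against, with a bound rewritten later. The 8 sequences of miR-18a, miR-20a and miR-92a arms, some of them forms of the same arm, had a median of -0.19 (SD 0.40). It was 0.01 without 1 sequence named for another gene copy. The miR-19a 5p arm had 603 and 551 reads at 0 and 6.25 mg/L. The 8 sequences split by miRNA, with means over both doses of -0.55 to -0.39 for miR-92a and 0.01 to 0.47 for miR-18a and miR-20a. Their median thus depends on how many miR-92a sequences are counted. The lower miR-92a sequences go part of the way with less of the shared transcript. Base composition and length stay open: miR-19a and miR-19b ranked at the 3.03rd to 6.82nd percentiles of sequences of like length and GC content, above the 2.5th set beforehand, though miR-19a at 6.25 mg/L (-1.27) lay below their interpolated lower limit of -1.10. The test added later points away from them, as such sequences had medians no lower than -0.11 (SD 0.64). Both treated libraries were close (mean log2 ratio 0.16), so a peculiarity of the single control library and a response to parental exposure cannot be told apart.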
